A study of Mus musculus with 10 samples.

How the data were processed

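RNA from 10 samples of mouse brain tissue was profiled on Illumina Mouse-6 arrays after Trizol extraction and labelling of amplified cRNA, per the labels. Each of the 10 arrays is the only one of its genotype and condition. The labels do not say whether an array held RNA of 1 mouse or of a pool, nor whether both hemispheres of a genotype and protocol came from the same mice. Per the file headers and the values, the deposited non-normalized table holds a bead intensity per probe and array on the linear scale. The detection p-value that accompanies each deposited intensity runs as 1 minus p, since it rises with intensity on every array, and was turned round before use. The value table of the authors holds intensity on the linear scale, quantile-normalized by the authors in 5 pairs of arrays. Sorted values of the arrays of a pair were equal within 1% at all but a few ranks, against at most 56.1% of ranks between arrays of different pairs, so values of different pairs are not on a common scale. That table served only as an alternative. The software and settings the authors used are not stated.

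Intensities were background-corrected with limma 3.58.1 in R 4.3.3 (nec, with negative controls inferred from the detection p-values, offset 16), quantile-normalized and put on the log2 scale. Of 46373 probes, 29800 map to a single gene, 10 to several and 16563 to none. Of these, 29746 probes were matched to the RefSeq genes of GRCm38.p6, which served only for names, chromosomes and the order of genes, because the array files name no genome build. Probes with a detection p under 0.01 on at least 2 arrays were kept (16067 probes, of which 12571 named), and the brightest probe stood for each of 9352 genes. A gene was read as above background where the probe that stood for it had a detection p under 0.01. Where all arrays of 1 side were below background, the fold is a lower bound, taken on each of those arrays against the lowest detected level or the value of the probe itself, whichever was higher, and list medians use the fitted values of such genes. Where the value of the probe was higher on all of those arrays, the bound equals the fitted fold. Between 12811 and 16310 probes were above background per array.

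One additive limma model with 5 conditions and genotype was fitted to all arrays, with 4 residual degrees of freedom, and a model with a genotype-by-ipsilateral term had 3. With no replicates of a group, the residuals are differences between genotypes across conditions. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, for 23 of 24 lists with at least 5 measured members. The KO minus WT differences in ipsilateral tissue were given without a test, with list medians placed among 10000 random lists. The comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule took, among genes past the threshold with the same sign in every pair of arrays, the 12 highest and 12 lowest in each hemisphere comparison, 6 and 6 in the protocol and contralateral comparisons, and Cd93 with 10 and 10 in the genotype comparison. For the interaction it took 10 and 10 past the threshold. Where fewer than 3 passed in a direction, the 5 largest with the same sign in every pair were named as not passed. Without a test, the 8 highest and 8 lowest by the mean of both protocols were named. Of each list described, up to 4 members with the largest change were named. Cd93, Ccl21a, Ccl21b, Ccl21c, Il1b, Il6, Tnf and Gfap were always to be given, but no probe was assigned to Ccl21c. Predicted transcripts were skipped.

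The lists were chemokines, cytokines and their receptors, resting microglia, phagocyte activation, blood-borne myeloid cells, lymphocytes, complement, interferon response, antigen presentation, reactive and resting astrocytes, endothelium, activated endothelium and adhesion, extracellular matrix and scar, general, striatal and cortical neurons, other brain regions, oligodendrocytes and myelin, choroid plexus and ependyma, cell cycle, stress and injury, immediate early genes and circulating blood. Of the measured members, another list also held 6 of reactive astrocytes, 5 of stress, 3 each of blood-borne myeloid cells, activated endothelium, matrix and cortical neurons, 2 each of cytokines, resting microglia, interferon response, antigen presentation, resting astrocytes, endothelium and immediate early genes, 1 each of phagocyte activation, general neurons and other regions, and none of the rest. Lists of 6 lymphatic and 15 glucocorticoid-responsive genes were added for the closing section. The alternatives were no background correction, median centring, the value table of the authors, no detection filter, detection on all 10 arrays, every probe, a variance trend with a robust prior, smaller sets of arrays, genotype alone, the protocols as repeats, an estimated correlation for lists, and each array left out in turn. A genotype count without chromosome 2 and the chemokine list without its Ccl21 genes were added after seeing the data. So were 2 settings in case both hemispheres came from the same mice. The first, for all comparisons, took the 6 combinations of genotype and protocol as a random block with a correlation estimated by limma (0.315, and 0.370 in the interaction model). The second averaged those hemispheres before the genotype comparison. No batch is named in the labels, so none was modelled. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

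The pipeline was tested on simulated data of 9352 genes, 200 of them changed. In the genotype comparison it recovered 71.6% of genes changed by 0.5 log2 units, 97.0% of those changed by 1 and 100% of those changed by 2. In the 48 h hemisphere comparison it recovered 26.9%, 89.6% and 100%, with 7.69% of its calls false, and in the interaction 4.48%, 50.7% and 92.4%. In the protocol difference it recovered 8.96%, 58.2% and 95.5%. In 20 simulations of the genotype comparison with independent genes, camera called 0 of 23 lists with either setting. Independent genes cannot show whether the preset correlation is too low for real, correlated ones. Over the 16 ways to split the real arrays within conditions, the real one included, a median of 9 lists passed at the preset correlation. All of these splits hold unequal numbers of KO and WT arrays on a side, so they are not free of genotype. In 20 simulations with a planted correlation of 0.4 within blocks, estimated at 0.341 on average, 13.6% of genotype calls were false without the block and 6.17% with it.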

Results

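Gene expression was measured in mouse brain on 10 Illumina Mouse-6 bead arrays, 1 for each combination of 2 genotypes and 5 conditions. The genotypes were wild type (WT) and knockout (KO) of Cd93, a gene for a membrane glycoprotein of endothelial and myeloid cells. The mice were 10 weeks old. In each genotype, 1 array came from untreated brain and 4 came from mice with middle cerebral artery occlusion (MCAo), a model of stroke in which the vessel is closed for a time and then reopened. Under the 48 h protocol the occlusion lasted 60 min and tissue was taken after 48 h of reperfusion. Under the 72 h protocol it lasted 30 min, with 72 h of reperfusion. The ipsilateral hemisphere, on the side of the occlusion, and the contralateral hemisphere were profiled separately. Between 12811 probes (KO untreated) and 16310 probes (KO ipsilateral, 48 h protocol) of 46373 stood above background, with median raw intensities from 51.4 to 58.9, and 9352 genes were tested. Changes are log2 differences of normalized intensity with the standard error of the limma model. A fold given as at least a value bounds the mean change with respect to background and does not cover the spread between arrays. No group was replicated, so adjusted p-values measure how steady a difference was across genotypes or conditions. Whether an array held 1 mouse or a pool, and whether both hemispheres came from the same mice, is not given. If they did, the arrays are not independent, and the p-values between genotypes are too small. The number of arrays limits the precision throughout.

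Cd93 signal was lower in KO than in WT brain in all 5 conditions, by 1.53 ± 0.18 on average (limma adjusted p = 0.00221). The log2 intensity of the Cd93 probe in WT brain was 6.92 in untreated tissue, 6.38 and 8.66 in the contralateral and ipsilateral hemispheres of the 48 h protocol, and 6.17 and 7.83 in those of the 72 h protocol. The matching KO values were 5.33, 5.39, 6.23, 5.10 and 6.24, of which only the ipsilateral values, 6.23 and 6.24, stood above background. The position of the probe relative to the deleted part of the gene is not given. Ipsilateral Cd93 signal was higher than contralateral signal by 1.56 ± 0.28 under the 48 h protocol (adjusted p = 0.00454) and by 1.40 ± 0.28 under the 72 h protocol (adjusted p = 0.00797). These are means over WT and the knockout, so they understate the WT change. In WT the differences were 2.28 and 1.66, against 0.84 and 1.14 in KO, where contralateral signal was below background. The genotype call for Cd93 was lost when the condition was left out of the model (-1.53, adjusted p = 0.607). The call for the 48 h protocol was lost without the WT contralateral array (1.22, adjusted p = 0.051). That for the 72 h protocol was lost without its KO ipsilateral (1.43, adjusted p = 0.0616), WT ipsilateral (1.37, adjusted p = 0.0507) or WT contralateral array (1.11, adjusted p = 0.0751), and with no detection filter (adjusted p = 0.052), and a second Cd93 probe did not pass there (0.62, adjusted p = 0.152).

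**Figure D1:**
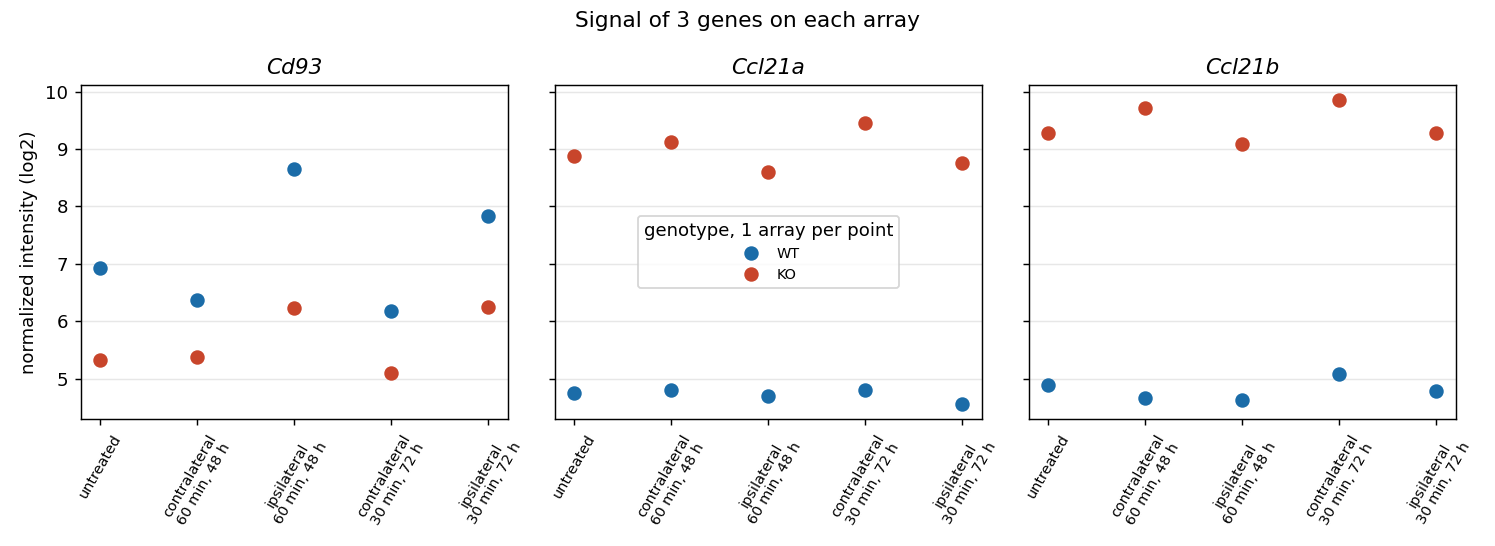
Normalized log2 intensity (vertical axis) of Cd93, Ccl21a and Ccl21b on each of the 10 arrays by condition (horizontal axis), 1 point per array, WT in blue and KO in red. Cd93 was lower in KO in all 5 conditions, and Ccl21a and Ccl21b were above background on the 5 KO arrays only.

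The first comparison asked which genes differ between the hemispheres after 60 min of MCAo and 48 h of reperfusion. The inflammatory mediators Cxcl1 (at least 16.8-fold higher, adjusted p = 0.000206) and Il11 (at least 10.4-fold higher, adjusted p = 3.01e-05), a neutrophil-attracting chemokine and a cytokine of the interleukin-6 family, led the genes higher in ipsilateral tissue. The bound of Cxcl1 equals its fitted mean, and its log2 difference was 3.53 in KO and 4.61 in WT. Myeloid genes followed, with Ms4a6d (3.45 ± 0.22, adjusted p = 3.01e-05) and the lectin gene Lgals3 (3.41 ± 0.21, adjusted p = 3.01e-05). The enzyme and matrix genes Tgm1 (3.38), Tgfbi (3.26) and Timp1 (3.04) and the cytoskeletal gene Tubb6 (at least 10.3-fold) were higher as well. The B-cell and microglial receptor gene Cd72 (at least 8.93-fold), the secreted Lcn2 (3.13) and Ccl12 (3.10), and the haem oxygenase gene Hmox1 (at least 8.13-fold) completed the 12 largest increases. The largest decreases were in the hypothalamic peptide genes Oxt (-2.18 ± 0.51, adjusted p = 0.017) and Avp (-1.49 ± 0.44, adjusted p = 0.0403), and in Rgs9 (-1.51 ± 0.17, adjusted p = 0.000341), which restrains dopamine signalling in the striatum. Ido1 (-1.46), Gpr6 (at least 2.29-fold lower), Ppp1r1b (-1.23), Syndig1l (-1.19), Rxrg (-1.18), Otof (-1.16), Nr1d2 (-1.04) and Hes5 (-0.99) were also lower. Trappc13 was lower by 1 of its 2 probes (-1.22), and its other probe, detected on all 10 arrays, went the other way (0.42, adjusted p = 0.0932). Il1b was higher (at least 1.91-fold, adjusted p = 0.00111), as was the astrocyte filament gene Gfap (1.61 ± 0.15), whereas Il6 and Tnf stayed at background on all 10 arrays.

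Genes of reactive astrocytes were the group with the highest median in this comparison. Of 29 measured, 26 passed the threshold as higher and none as lower (28 adjusted over the list alone), with Tgm1 (3.38), Lcn2 (3.13) and Timp1 (3.04) among them (median 1.61, camera adjusted p = 4.06e-21, adjusted p = 0.102 with an estimated correlation). All 26 measured interferon-response genes were higher, also adjusted over the list alone (26), such as Ifitm3 (2.05), Ifi27l2a (at least 3.72-fold) and Irgm1 (1.93) (median 1.23, camera adjusted p = 3.71e-21, adjusted p = 0.0568 with an estimated correlation). Of 27 phagocyte activation genes, 24 were higher and 1 was lower (26 and 1 adjusted over the list alone), with Lgals3 (3.41), Hmox1 (at least 8.13-fold) and Lyz2 (2.89) as examples (median 1.38, camera adjusted p = 3.71e-21, adjusted p = 0.0501 with an estimated correlation). Cell cycle genes were higher in 26 of 30 cases (27 adjusted over the list alone), including Uhrf1 (2.17), Cdk1 (at least 2.98-fold) and Prc1 (1.97) (median 1.01, camera adjusted p = 1.11e-18, adjusted p = 0.0568 with an estimated correlation).

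Chemokines were higher in 10 of 18 cases and lower in 1 (10 and 1 adjusted over the list alone), with Cxcl1 (at least 16.8-fold), Ccl12 (3.10) and Ccl7 (at least 7.1-fold) (median 0.96, camera adjusted p = 0.000886, adjusted p = 0.0911 with an estimated correlation). Cytokines and their receptors were higher in 12 of 20 cases (13 higher and 1 lower adjusted over the list alone), with Il11 (at least 10.4-fold), Il33 (1.74) and Osmr (1.67) (median 0.86, camera adjusted p = 6.82e-09, adjusted p = 0.113 with an estimated correlation). Blood-borne myeloid genes were higher in 11 of 15 cases and lower in 1 (13 and 1 adjusted over the list alone), with Lcn2 (3.13), Arg1 (at least 4.92-fold) and S100a8 (2.25) (median 1.09, camera adjusted p = 6.8e-07, adjusted p = 0.176 with an estimated correlation). Resting microglia markers were higher in 9 of 16 cases and lower in 1 (10 and 1 adjusted over the list alone), with Fcrls (1.69) and Olfml3 (1.38) (median 0.51, camera adjusted p = 0.000814, adjusted p = 0.176 with an estimated correlation). Complement genes were higher in 4 of 10 cases and lower in 1, the same adjusted over the list alone, with C1qc (1.26), C1qb (1.23) and C1qa (0.97) (median 0.24, camera adjusted p = 0.00711, adjusted p = 0.279 with an estimated correlation). Antigen presentation genes were higher in 12 of 21 cases and lower in 1, the same adjusted over the list alone, with Cd74 (1.82), H2-Ab1 (at least 3.3-fold) and Psmb9 (at least 2.54-fold) (median 0.53, camera adjusted p = 3.35e-06, adjusted p = 0.0568 with an estimated correlation).

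Vessel and matrix genes were mostly higher. Endothelial genes were higher in 16 of 26 cases and lower in 1 (18 and 1 adjusted over the list alone), with Emcn (1.47), Mmrn2 (1.38) and Vwf (1.31) (median 0.71, camera adjusted p = 5.49e-08, adjusted p = 0.176 with an estimated correlation). Genes of activated endothelium and adhesion were higher in 15 of 21 cases (17 adjusted over the list alone), with Ch25h (2.99), Selp (at least 6.41-fold) and Cd44 (2.47) (median 0.93, camera adjusted p = 6.65e-10, adjusted p = 0.102 with an estimated correlation). Matrix and scar genes were higher in 17 of 28 cases (19 higher and 1 lower adjusted over the list alone), with Tgfbi (3.26), Timp1 (3.04) and Mmp3 (at least 4.76-fold) (median 0.84, camera adjusted p = 6.44e-10, adjusted p = 0.176 with an estimated correlation). Myelin genes were higher in 10 of 27 cases (12 higher and 2 lower adjusted over the list alone), with Trf (1.53), Opalin (0.86) and Cldn11 (0.65) (median 0.35, camera adjusted p = 0.000886, adjusted p = 0.176 with an estimated correlation). Stress genes were higher in 7 of 22 cases, the same adjusted over the list alone, with Hmox1 (at least 8.13-fold), Hspb1 (1.85) and Casp8 (at least 2.65-fold) (median 0.26, camera adjusted p = 0.00711, adjusted p = 0.176 with an estimated correlation). Choroid plexus genes were higher in 3 of 18 cases (6 adjusted over the list alone), with Igfbp2 (0.64), Otx2 (at least 1.32-fold) and Wfdc2 (0.62) (median 0.32, camera adjusted p = 0.02, adjusted p = 0.174 with an estimated correlation).

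Striatal neuron genes were lower in 19 of 25 cases and higher in none (23 adjusted over the list alone), with Rgs9 (-1.51), Ido1 (-1.46), Gpr6 (at least 2.29-fold) and Ppp1r1b (-1.23) (median -0.63, camera adjusted p = 9.15e-13, adjusted p = 0.102 with an estimated correlation). General neuronal and synaptic genes were lower in 8 of 34 cases, the same adjusted over the list alone, with Dlg4 (-0.71), Camk2a (-0.67) and Ntrk2 (-0.64), and their median of -0.26 became 0.13 under median centring (camera adjusted p = 0.000227, adjusted p = 0.0736 with an estimated correlation). Cortical neuron genes were lower in 6 of 21 cases and higher in 1 (7 and 1 adjusted over the list alone), with Nr4a2 (-0.81), Kcnh3 (-0.77) and Lamp5 (-0.65), and their median of -0.24 became 0.18 under median centring (camera adjusted p = 0.0135, adjusted p = 0.176 with an estimated correlation). The lists for other brain regions (median -0.14, and 0.30 under median centring, camera adjusted p = 0.211), resting astrocytes (median 0.14, camera adjusted p = 0.452), circulating blood (median 0.27, camera adjusted p = 0.423) and immediate early genes did not pass. Immediate early genes had a median of -0.044 against an upward camera direction, and a median of 0.42 under median centring (camera adjusted p = 0.632). The lymphocyte list had 3 measured members, Cd8b1, Il2rb and Thy1, and none passed in any comparison.

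In all, 1939 of 9352 genes passed, 1185 higher (61.1%) and 754 lower, and 325 and 11 of these changed at least 2-fold. Median centring in place of quantile normalization brought the median of all genes from -0.020 to 0.43 and gave 4925 genes, 4882 higher (99.1%) and 43 lower, so the balance of directions depends on the scaling. None of the 19 list calls held with an estimated correlation. The count was 585 without the KO ipsilateral array of the protocol, 753 without the WT ipsilateral, 748 without the WT contralateral and 1016 without the KO contralateral array. Oxt and Avp lost their calls without the KO ipsilateral (-1.74 and -0.97), KO contralateral (-1.98 and -1.25) or WT contralateral array (-2.38 and -1.73) of the protocol, and Avp without either untreated array (adjusted p = 0.0541). Nr1d2 lost its call without the KO ipsilateral (-0.86) or WT contralateral array (-0.68), and Gpr6 without the KO ipsilateral array (adjusted p = 0.0532). With no detection filter Oxt, Avp and Nr1d2 lost their calls (adjusted p = 0.0754, 0.132 and 0.0545), and Oxt and Avp with a variance trend (adjusted p = 0.119 and 0.159). The list members Arg1 and S100a8 lost theirs under both settings (adjusted p from 0.0605 to 0.201).

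The next comparison was of the hemispheres after 30 min of MCAo and 72 h of reperfusion. Genes of phagocytes were highest, with Lgals3 (4.63 ± 0.21, adjusted p = 2.18e-06), Gpnmb (3.99 ± 0.17, adjusted p = 1.64e-06) and the lysozyme gene Lyz2 (3.87 ± 0.15, adjusted p = 1.02e-06). Cd72 (at least 12.9-fold), Plin2 (3.54), Ms4a6d (3.43) and Fcgr4 (3.43) followed, then Tgm1 (at least 9.8-fold), Klk6 (3.26), Ccl4 (3.18), Tgfbi (3.18) and Prc1 (3.15). Several of the largest decreases were in genes of striatal neurons, with Ido1 (-1.72 ± 0.18, adjusted p = 0.000142), Rgs9 (-1.48 ± 0.17, adjusted p = 0.000242) and the enkephalin precursor gene Penk (-1.28). The dopamine receptor genes Drd1 (-1.18) and Drd2 (at least 1.95-fold) were lower, as were Gpr6 (at least 2.25-fold), Ppp1r1b (-1.28), Syndig1l (-1.12), Rxrg (-1.12), Rem2 (-1.04), Actn2 (-0.99) and Gng7 (-0.94). Gfap was higher (1.46 ± 0.15, adjusted p = 0.00012). Il1b stayed below background on the 4 arrays of this protocol (adjusted p = 0.121).

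Phagocyte activation genes were higher in 26 of 27 cases, the same adjusted over the list alone, with Lgals3 (4.63), Gpnmb (3.99) and Lyz2 (3.87) (median 1.89, camera adjusted p = 1.98e-33, adjusted p = 0.0131 with an estimated correlation). Cell cycle genes were higher in 26 of 30 cases (28 adjusted over the list alone), with Prc1 (3.15), Cdca3 (3.05) and Tk1 (at least 5.2-fold) (median 1.496, camera adjusted p = 1.65e-27, adjusted p = 0.0306 with an estimated correlation). Interferon-response genes were higher in 24 of 26 cases (26 adjusted over the list alone), with Ifi27l2a (2.78), Ifi30 (2.74) and Bst2 (2.20) (median 1.27, camera adjusted p = 1.34e-24, adjusted p = 0.0447 with an estimated correlation). Antigen presentation genes were higher in 14 of 21 cases (15 adjusted over the list alone), with H2-Ab1 (at least 5.26-fold), Cd74 (2.06) and Psmb8 (1.88) (median 0.86, camera adjusted p = 1.28e-13, adjusted p = 0.0131 with an estimated correlation). General neuronal genes were lower in 7 of 34 cases, the same adjusted over the list alone, with Shank3 (-0.67), Slc12a5 (at least 1.49-fold) and Dlg4 (-0.56) (median -0.24, camera adjusted p = 1.88e-05, adjusted p = 0.0477 with an estimated correlation). These 5 lists passed by either setting of camera.

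Reactive astrocyte genes were higher in 22 of 29 cases (28 adjusted over the list alone), with Tgm1 (at least 9.8-fold), Emp1 (3.01) and Timp1 (2.80) (median 1.41, camera adjusted p = 2.53e-22, adjusted p = 0.0812 with an estimated correlation). Resting microglia markers were higher in 12 of 16 cases, the same adjusted over the list alone, with Fcrls (2.42), Trem2 (1.82) and Rnase4 (at least 3.31-fold) (median 0.77, camera adjusted p = 1.15e-10, adjusted p = 0.076 with an estimated correlation). Complement genes were higher in 6 of 10 cases, the same adjusted over the list alone, with C1qc (1.89), C1qa (1.86) and C1qb (1.83) (median 0.53, camera adjusted p = 4.13e-06, adjusted p = 0.117 with an estimated correlation). Matrix and scar genes were higher in 19 of 28 cases (21 adjusted over the list alone), with Tgfbi (3.18), Lgals1 (3.01) and Timp1 (2.80) (median 1.11, camera adjusted p = 6.25e-13, adjusted p = 0.113 with an estimated correlation). Striatal neuron genes were lower in 22 of 25 cases (24 adjusted over the list alone, median -0.78, camera adjusted p = 7.92e-17, adjusted p = 0.076 with an estimated correlation). Cortical neuron genes were lower in 6 of 21 cases (8 adjusted over the list alone), with Emx1 (-0.86), Kcnh3 (-0.65) and Nr4a2 (-0.60) (median -0.28, camera adjusted p = 0.000366, adjusted p = 0.0812 with an estimated correlation). Chemokines were higher in 8 of 18 cases and lower in 1 (10 and 5 adjusted over the list alone), with Ccl4 (3.18), Cxcl16 (at least 6.71-fold) and Ccl12 (2.69) (median 0.78, camera adjusted p = 0.00238, adjusted p = 0.0812 with an estimated correlation). Cytokines and their receptors were higher in 13 of 20 (15 adjusted over the list alone), with Il11 (at least 2.56-fold), Tnfrsf1a (1.53) and Osmr (1.495) (median 0.82, camera adjusted p = 1.46e-10, adjusted p = 0.0812 with an estimated correlation). Blood-borne myeloid cells were higher by camera (6 of 15 higher, 11 adjusted over the list alone, median 0.77, camera adjusted p = 4.05e-07, adjusted p = 0.167 with an estimated correlation). So was endothelium (12 of 26 higher, 18 adjusted over the list alone, median 0.60, camera adjusted p = 3.33e-08, adjusted p = 0.167 with an estimated correlation). Activated endothelium passed too (14 of 21 higher, 16 adjusted over the list alone, median 0.81, camera adjusted p = 5.04e-09, adjusted p = 0.0812 with an estimated correlation). Myelin genes were on the higher side (12 of 27 higher, 15 adjusted over the list alone, median 0.37, camera adjusted p = 2.16e-07, adjusted p = 0.0812 with an estimated correlation). Stress genes were the last of these (5 of 22 higher, 8 adjusted over the list alone, median 0.20, camera adjusted p = 0.00491, adjusted p = 0.167 with an estimated correlation). In the list of other brain regions, which did not pass (median -0.11, camera adjusted p = 0.38), the serotonergic genes Tph2 (at least 4.33-fold) and Slc6a4 (at least 2.97-fold) were higher. Their contralateral signal lay below that of untreated brain, for Tph2 at 5.19 in KO and 5.64 in WT against 6.97 and 5.93. For Slc6a4 the values were 4.72 and 4.99 against 6.04 and 5.22. Whether the samples of both sides held the same brain regions was not tested, which bears on these genes and on Oxt and Avp at 48 h.

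Of 9352 genes, 1348 passed, 962 higher (71.4%) and 386 lower, and 400 and 9 of these changed at least 2-fold. Median centring gave 1118 higher (94.1%) and 70 lower, and the value table of the authors gave 799 higher (83.6%) and 157 lower. In all, 18 lists passed at the preset correlation. The count was 582 without the KO ipsilateral array of this protocol, 720 without its KO contralateral and 882 without its WT contralateral array. The 24 genes named for their rank kept their calls under every alternative run, each array left out included.

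**Figure D2:**
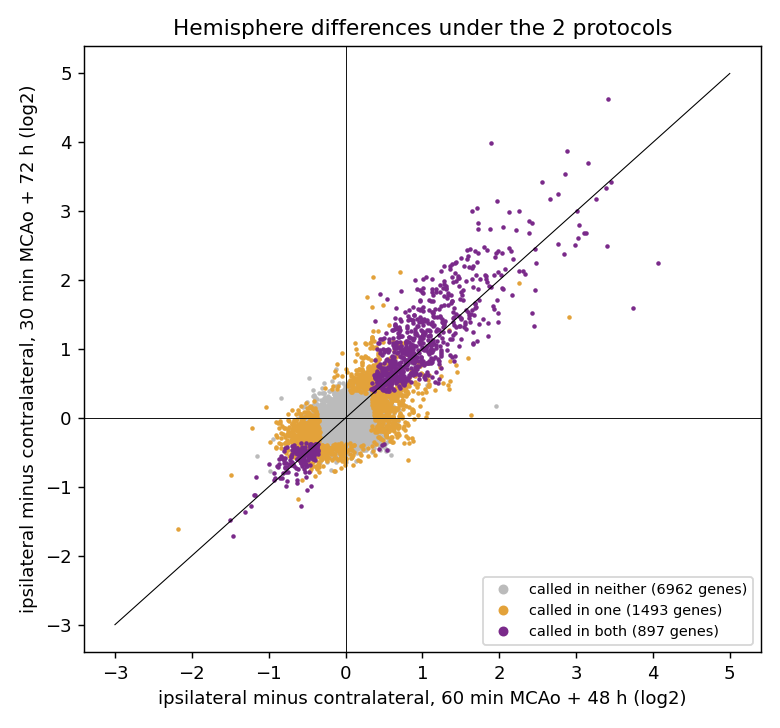
Ipsilateral minus contralateral log2 difference of 9352 genes under the 48 h protocol (horizontal axis) and the 72 h protocol (vertical axis), 1 point per gene, coloured by whether the gene passed in neither, in 1 or in both comparisons, with the line of equal change. Genes that passed in both lay mostly in the upper right, with 722 higher and 171 lower under both protocols.

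The protocols were then set side by side, and occlusion time and reperfusion time changed together between them. The largest values below 0 were those of the phagocyte gene Gpnmb at -2.10 ± 0.24 (48 h minus 72 h, adjusted p = 0.0508), followed by Apoc2 (-1.68), Slc6a4 (-1.47), Tph2 (-1.41) and Arl11 (-1.37). In the other direction stood Il11 (2.14 ± 0.34, adjusted p = 0.0954), Cxcl1 (1.83), Pcp2 (1.60), Selp (1.45) and Ssr3 (1.42). None of these 10 genes passed with the brightest probe of each. For Gpnmb this depends on the probe, as its 2 other probes, above background on 4 and 2 arrays, passed (-2.61, adjusted p = 0.000534, and -2.09, adjusted p = 0.00116). Pcp2 was above background on 2 of the 10 arrays and Selp and Ssr3 on 3, so 2 of the 4 hemisphere differences behind Pcp2 and 1 each behind Selp and Ssr3 hold no detected value. Il11, Cxcl1, Apoc2 and Arl11 were above background on the 4 ipsilateral arrays only, and Slc6a4 and Tph2 on neither contralateral array of the 72 h protocol. Gpnmb apart, the size of these values is therefore uncertain. The value of Selp was 0.18 without the WT ipsilateral array of the 72 h protocol and 2.72 without the KO ipsilateral array, and that of Cxcl1 was 0.97 and 2.69. Limma called 0 genes, with 1018 at an unadjusted p under 0.05, and between 0 and 7 under the alternatives of normalization, filter and model fixed beforehand. With the hemispheres of a genotype and protocol as a random block, an alternative added after seeing the data, it called 28, 11 higher and 17 lower. Across genes, which are not independent replicates, the hemisphere differences of the protocols had a Pearson r of 0.798. There were 722 genes higher under both protocols, against 122 for independent sets, and 171 lower under both, against 31.1. The sets are not independent, because both comparisons use the same residual spread of each gene, which raises the overlap in advance.

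Of the lists, 5 were lower under the 48 h than the 72 h protocol by camera, although no single member passed over all genes. The first was phagocyte activation (11 of 27 lower adjusted over the list alone, median -0.60, camera adjusted p = 1.13e-13, adjusted p = 0.0652 with an estimated correlation). The others were cell cycle (8 of 30 lower adjusted over the list alone, median -0.43, camera adjusted p = 9.71e-10, adjusted p = 0.161 with an estimated correlation), then resting microglia (2 of 16 lower adjusted over the list alone, median -0.37, camera adjusted p = 1.53e-08, adjusted p = 0.161 with an estimated correlation). Complement (4 of 10 lower adjusted over the list alone, median -0.31, camera adjusted p = 0.00136, adjusted p = 0.654 with an estimated correlation) had a median of 0.023 under median centring, which brought the median of all genes from 0.0010 to 0.33. Antigen presentation (0 of 21 lower adjusted over the list alone, median -0.28, camera adjusted p = 4.68e-06, adjusted p = 0.0652 with an estimated correlation) had a median of 9e-04 under that scaling. Under it the medians were also nearer 0 for phagocyte activation (-0.26), cell cycle (-0.20) and resting microglia (-0.0049).

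**Figure D3:**
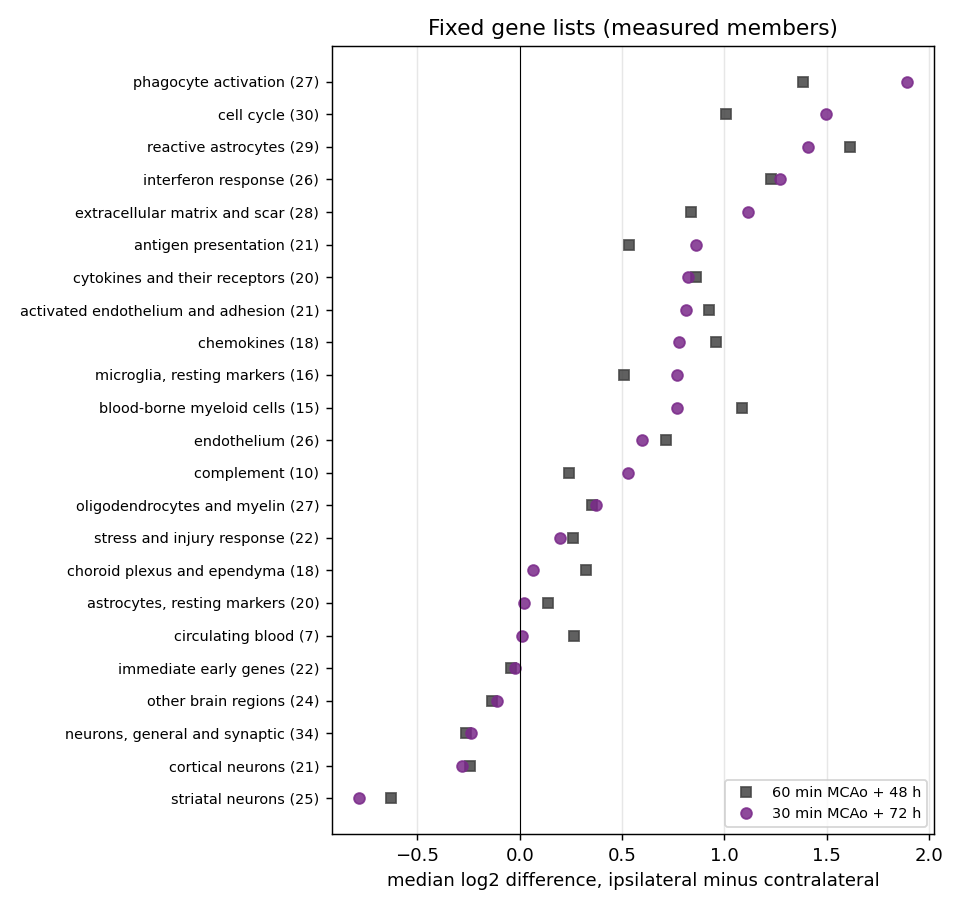
Median ipsilateral minus contralateral log2 difference (horizontal axis) of each of 23 gene lists (vertical axis, measured members in brackets), squares for the 48 h protocol and circles for the 72 h protocol. Under both protocols the phagocyte, cell cycle, reactive astrocyte and interferon lists lay above 1 and the striatal list was lowest, whereas the general and cortical neuron lists, the list of other regions and immediate early genes, below 0 here at 48 h, were above 0 there under median centring, as were immediate early genes at 72 h.

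The contralateral hemispheres were compared with untreated brain to see what differs away from the occluded side. Under the 48 h protocol the lipid droplet gene Plin4 (at least 12.9-fold higher, adjusted p = 0.000735), the iron-binding lipocalin gene Lcn2 (at least 5.75-fold higher, adjusted p = 0.0115) and the chemokine gene Ccl4 (at least 3.59-fold higher, adjusted p = 0.0115) were higher. The acute-phase gene Serpina3n (2.24 ± 0.23, adjusted p = 0.00594), the hypoxia-related gene Hif3a (at least 4.1-fold higher, adjusted p = 0.000735) and Lgals3 (at least 3.04-fold) were also higher. Gfap was higher by 1.24 ± 0.15 (adjusted p = 0.0115), but its other probe, above background on 9 arrays, did not pass (0.79, adjusted p = 0.24). The growth hormone gene Gh was lower (at least 3.05-fold, adjusted p = 8.22e-05), as were the activity-regulated gene Npas4 (-1.17), the myelin gene Opalin (-1.01), Myl4 (-0.94) and Tubb2b (-0.84). Gh was above background on the 2 untreated arrays only and on no hemisphere array, ipsilateral ones included, so its difference is not particular to contralateral tissue. Reactive astrocyte genes were higher in 6 of 29 cases (16 adjusted over the list alone), with Lcn2 (at least 5.75-fold), Serpina3n (2.24), Gfap (1.24) and Osmr (at least 2.27-fold) (median 0.67, camera adjusted p = 2.63e-15, adjusted p = 0.491 with an estimated correlation). Phagocyte activation genes were higher in 2 of 27 cases (10 adjusted over the list alone), with Lgals3 (at least 3.04-fold) and Tlr2 (at least 2.31-fold) (median 0.26, camera adjusted p = 5.65e-07, adjusted p = 0.391 with an estimated correlation). Lower by camera were striatal neurons (median 0.23 with the value table of the authors, otherwise median -0.12, camera adjusted p = 0.00172, adjusted p = 0.491 with an estimated correlation) and myelin (0.24 with that table, otherwise median -0.13, camera adjusted p = 0.0273, adjusted p = 0.491 with an estimated correlation). So was the list of immediate early genes (0.16 with that table, otherwise median -0.20, camera adjusted p = 0.0148, adjusted p = 0.515 with an estimated correlation). In all, 33 genes passed, 28 higher and 5 lower, and 12 lists by camera, none with an estimated correlation. The value table of the authors, which was scaled within pairs of arrays, gave 3603 genes, 3596 higher and 7 lower, and brought the median of all genes from 0.0080 to 0.32. The count was 3 without the KO contralateral or the KO untreated array and 10 without the WT contralateral array, and 51 without the WT untreated array or either ipsilateral array of the 72 h protocol. Lcn2, Serpina3n and Gfap lost their calls without the KO contralateral (adjusted p = 0.107, 0.0819 and 0.0893) or the KO untreated array (0.159, 0.0865 and 0.159). Ccl4, Lgals3, Osmr and Myl4 also lost theirs without the WT contralateral array, and Tlr2, Opalin, Tubb2b and Npas4 without the WT untreated array too (adjusted p from 0.0519 for Opalin to 0.285 for Npas4 over these arrays). Npas4 lost its call without either ipsilateral array of the 48 h protocol as well (adjusted p = 0.0615). Hif3a was at 0.030 with detection on all 10 arrays, where its other probe stood for it, so its change was seen with 1 of its 2 probes. With no detection filter only 1 gene passed, and all of the named genes but Gh lost their calls, Plin4 among them (adjusted p from 0.0673 for Hif3a to 0.187 for Npas4). Lcn2 also lost its call with a variance trend (adjusted p = 0.094). The other probe of Ccl4, above background on 4 arrays, was at 0.19.

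Under the 72 h protocol contralateral tissue was again compared with untreated brain. Plin4 (at least 10.6-fold higher, adjusted p = 0.00124), Lcn2 (at least 3.34-fold higher, adjusted p = 0.0357) and Hif3a (at least 4.18-fold higher, adjusted p = 0.000971) led, followed by Serpina3n (1.77), Ccl4 (at least 2.11-fold) and the sulfotransferase gene Sult1a1 (1.55). Gfap was higher by 1.28 ± 0.15 (adjusted p = 0.0176), and its other probe did not pass (0.91, adjusted p = 0.0743). Gh was lower (at least 3.2-fold, adjusted p = 7.65e-05), as were Zfp955a (-1.02), Thoc2 (-1.02), Gabrb2 (-0.93) and Atp2b2 (-0.91). The pericyte gene Rgs5 was lower by 1 of its 2 probes (-0.90), whereas the other, detected on all 10 arrays, was at 0.19. Reactive astrocyte genes were higher in 7 of 29 cases (10 adjusted over the list alone, median 0.43, camera adjusted p = 2.35e-06, adjusted p = 0.493 with an estimated correlation). Phagocyte activation genes were higher in 4 of 27 (13 higher and 2 lower adjusted over the list alone, median 0.46, camera adjusted p = 5.98e-06, adjusted p = 0.493 with an estimated correlation). Interferon-response genes were higher in 1 of 26 cases, Lgals3bp (0.62), and in 6 adjusted over the list alone (median 0.24, camera adjusted p = 0.000765, adjusted p = 0.493 with an estimated correlation). Immediate early genes were lower in 1 of 22 cases, Nr4a2 (-0.87, but -0.19 with its other probe), and in 4 adjusted over the list alone (median -0.42, camera adjusted p = 0.000765, adjusted p = 0.493 with an estimated correlation). The myelin list had a lower median (median -0.15, camera adjusted p = 0.0299, adjusted p = 0.493 with an estimated correlation), which was 0.024 under median centring and 0.14 with the value table of the authors. In all, 131 genes passed, 103 higher (78.6%) and 28 lower, and 10 lists by camera, none with an estimated correlation. Without background correction 132 genes were higher (65.0%) and 71 lower. Median centring gave 145 (90.1%) and 16, with a median of all genes of 0.17 in place of 0.024. The value table of the authors gave 2050 (98.9%) and 23, with a median of 0.27. The count was 4 without the KO untreated array, 11 without the WT contralateral and 25 without the KO contralateral array of this protocol, 20 without either ipsilateral array of the 48 h protocol and 63 without either of the 72 h protocol. Of the 12 genes named by rank, those other than Gh, Plin4 and Hif3a lost their calls without the KO untreated array (adjusted p from 0.138 for Sult1a1 to 0.261 for Zfp955a), as did Gfap (0.138). Lcn2, Gabrb2, Atp2b2, Rgs5, Zfp955a and Gfap did so without either contralateral array of the protocol, Thoc2 without the WT (adjusted p = 0.239) and Ccl4 and Sult1a1 without the KO contralateral array (adjusted p = 0.0673 and 0.0591). Ccl4, Zfp955a, Thoc2, Gabrb2, Atp2b2 and Rgs5 did so without the WT untreated array (adjusted p from 0.0536 for Gabrb2 to 0.0841 for Atp2b2). Lcn2, Ccl4, Zfp955a, Thoc2, Gabrb2 and Atp2b2 did so without either ipsilateral array of the 48 h protocol (adjusted p from 0.0546 for Lcn2 to 0.0799 for Zfp955a), and Ccl4, Zfp955a and Thoc2 without either of the 72 h protocol (adjusted p from 0.0515 for Zfp955a to 0.0625 for Thoc2). With its other probe, Hif3a was at 0.0057. Ccl4 was at 0.97 without the KO contralateral array of the protocol and at 2.33 without the WT contralateral array. With no detection filter 4 genes passed, and of the 12 genes named by rank and Gfap only Gh and Hif3a kept their calls (adjusted p of the others from 0.0807 for Plin4 to 0.125 for Zfp955a). With the hemispheres as a random block, added after seeing the data, 38 genes passed. Lcn2, Ccl4, Zfp955a, Thoc2, Gabrb2 and Atp2b2 lost their calls there (adjusted p from 0.0507 for Lcn2 to 0.067 for Zfp955a). Lcn2 and Ccl4 also lost theirs with a variance trend (adjusted p = 0.0985 and 0.0562), and Zfp955a and Thoc2 with every probe (adjusted p = 0.0527). The other probe of Ccl4 was at 0.087. Lgals3bp lost its call without any 1 array other than the contralateral arrays of the 48 h protocol (adjusted p from 0.052 to 0.172). Both contralateral comparisons used the same 2 untreated arrays. The labels name no sham-operated mice, so effects of the operation cannot be told apart from those of the occlusion.

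The comparison of KO with WT brain over all 5 conditions addressed the aim given by the title of the series. The chemokine genes Ccl21b (at least 21.1-fold higher, adjusted p = 7.29e-09) and Ccl21a (at least 15.4-fold higher, adjusted p = 1.21e-08), ligands of the receptor Ccr7, were above background on all 5 KO arrays and on none of the WT arrays. Next came the phospholipase gene Pla2g4e (2.13 ± 0.073, adjusted p = 2.16e-07), the kinase gene Stk4 (2.12 ± 0.074, adjusted p = 2.16e-07) and the ciliary neurotrophic factor receptor gene Cntfr (1.51 ± 0.13, adjusted p = 0.000204). Ppp1r16b (1.49), Plin4 (1.16), Sys1 (1.07), Slamf9 (0.82) and Lgals3 (0.77) were also higher. The brain glycogen phosphorylase gene Pygb (-2.21 ± 0.11, adjusted p = 3.15e-06) was lowest in KO, followed by Zcchc3 (-1.96 ± 0.13, adjusted p = 3.56e-05) and the methyl-cycle enzyme gene Ahcy (-1.78 ± 0.078, adjusted p = 1.4e-06). Ttpal (-1.69), Rbbp9 (-1.60), Tmem181a (-1.53), Pla2g4b (at least 2.05-fold), Zfp341 (-1.21) and Polr3f (at least 2.01-fold) were lower too. Zcchc3 and Ahcy were above background on 6 of the 10 arrays and Ttpal on 7, with most KO arrays below it, so the size of these values is uncertain. The same holds for Slamf9, above background on 6 arrays. Plin4 and Lgals3 were above background on neither untreated array, where their differences were 0.40 and 0.46, against up to 1.8 and 1.5 in other conditions. Il1b (adjusted p = 0.171) and Gfap (adjusted p = 0.809) did not pass.

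The genes that passed gathered on chromosome 2, which carries Cd93 in the mouse assembly GRCm38.p6. They made up 44 of the 754 tested genes there (5.84%). Apart from Cd93 itself, 43 of 753 passed on that chromosome and 65 of 8591 on the others (odds ratio 7.94, 95% interval 5.23 to 11.95, Fisher's exact two-sided p = 5.15e-20). This test, chosen after the result was seen, takes genes as independent. Neighbouring genes measured on the same arrays may not be, so the interval and p-value can overstate the precision. Pla2g4e, Stk4, Ppp1r16b, Sys1, Pygb, Zcchc3, Ahcy, Ttpal, Rbbp9, Pla2g4b, Zfp341 and Polr3f are all on chromosome 2, and Ccl21a, Ccl21b and Cntfr are on chromosome 4. Of the 13 called genes of chromosome 2 with a second detected probe, 10 had the same sign on it and 7 had a ratio of second to first probe under 0.25.

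**Figure D4:**
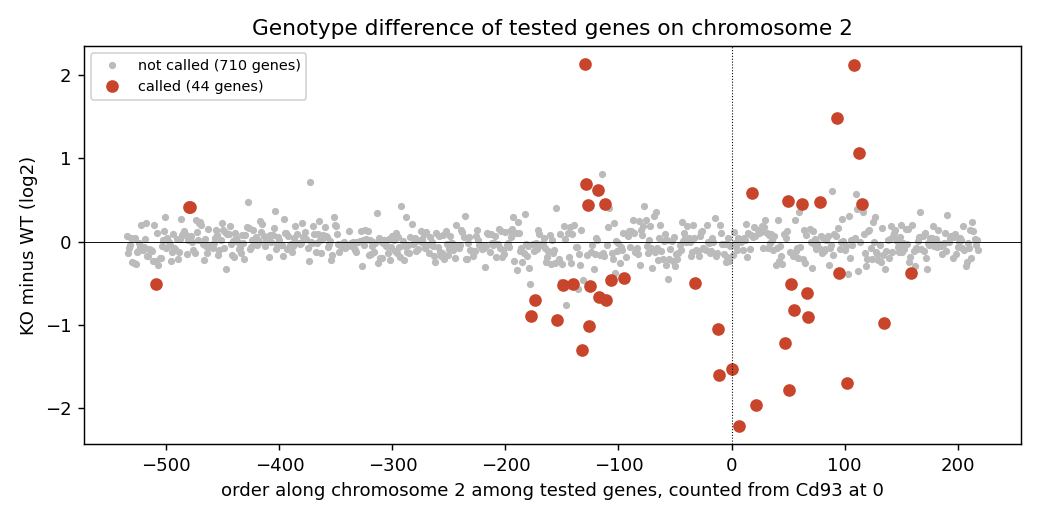
KO minus WT log2 difference (vertical axis) of the tested genes of chromosome 2 in their order along it, counted from Cd93 at 0 (horizontal axis), 1 point per gene, with the 44 genes that passed in red. They lay on both sides of Cd93 and in both directions, all but 3 of them between places -177 and 159 of that order.

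Phagocyte activation genes were higher in KO in 1 of 27 cases, Lgals3, and in 12 adjusted over the list alone, with 1 lower (median 0.23, camera adjusted p = 2.91e-07, adjusted p = 0.113 with an estimated correlation). Blood-borne myeloid genes were higher in 6 of 15 cases adjusted over the list alone and in 0 over all genes (median 0.39, camera adjusted p = 9.59e-05, adjusted p = 0.447 with an estimated correlation). The interferon list held Lgals3bp (0.37) as its only member past the threshold over all genes (5 adjusted over the list alone, median 0.19, camera adjusted p = 3.96e-05, adjusted p = 0.447 with an estimated correlation). Chemokines owed their 2 calls to Ccl21a and Ccl21b (5 adjusted over the list alone, median 0.37, camera adjusted p = 1.07e-05, adjusted p = 0.113 with an estimated correlation). No gene passed over all genes among reactive astrocytes (3 of 29 higher adjusted over the list alone, median 0.24, camera adjusted p = 4.1e-07, adjusted p = 0.447 with an estimated correlation). The same held for endothelium (5 of 26 higher adjusted over the list alone, median 0.14, camera adjusted p = 0.000108, adjusted p = 0.484 with an estimated correlation). Striatal neurons had a lower median in KO (median -0.15, camera adjusted p = 4.78e-05, adjusted p = 0.447 with an estimated correlation). Cortical neurons did too (median -0.084, camera adjusted p = 0.0165, adjusted p = 0.447 with an estimated correlation). In all, 12 lists passed at the preset correlation, but 3 of the 16 splits of the arrays within conditions, the real split included, gave as many. The median over the 16 splits was 9 lists, so list calls at the preset correlation were common also with the genotypes mixed. With 5 conditions every split leaves more arrays of 1 genotype on a side, so none of the 16 is free of the genotype difference.

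In all, 109 of 9352 genes passed, 50 higher in KO (45.9%) and 59 lower. The value table of the authors gave 79 higher (64.2%) and 44 lower. Leaving out any of the 8 hemisphere arrays lowered the count, to 47 without either ipsilateral and 49 without either contralateral array of the 48 h protocol, and to 44 without either ipsilateral and 56 without either contralateral array of the 72 h protocol. Plin4, Slamf9 and Lgals3 lost their calls when single arrays were left out. Plin4 did so without either contralateral array of the 48 h protocol (1.16, adjusted p = 0.0571) or either ipsilateral (0.998, adjusted p = 0.0613) or contralateral array (1.04, adjusted p = 0.0616) of the 72 h protocol. Slamf9 did so without either ipsilateral (0.84) or contralateral array (0.69) of the 48 h protocol or either contralateral array of the 72 h protocol (0.74). Lgals3 did so without either ipsilateral (0.83) or contralateral array (0.82) of the 48 h protocol or either ipsilateral array of the 72 h protocol (0.76). Lgals3bp lost its call without any 1 of the 10 arrays (adjusted p from 0.0697 to 0.126). With no detection filter Plin4, Slamf9, Lgals3 and Lgals3bp lost their calls (adjusted p = 0.104, 0.0957, 0.121 and 0.0508). Plin4, Slamf9 and Lgals3 also lost theirs when the condition was left out of the model. Ppp1r16b was at 0.065 with detection on all 10 arrays, where its other probe stood for it, and Ttpal was at -0.44 and -0.18 with its 2 other probes, detected on 3 and 5 arrays. With the hemispheres of a genotype and protocol as a random block (correlation 0.315), added after seeing the data, 52 genes passed, 29 of them on chromosome 2. With those hemispheres averaged first, also added then, 36 passed, 23 of them on chromosome 2. Slamf9 lost its call in the first (adjusted p = 0.0692), Plin4 in the second (0.0797), and Lgals3 (0.0692 and 0.0735) and Lgals3bp (0.111 and 0.197) in both.

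The last comparison asked whether the genotype difference in ipsilateral tissue departed from that in the other conditions. The myeloid genes Arg1 (1.77 ± 0.55), Fpr2 (1.40), Chil4 (1.30) and Clec4d (1.09, adjusted p = 0.193) and the plasma protein gene Itih4 (1.20) had the largest positive values, and none passed. Arg1 and Itih4 stood at 0.56 and 0.46 without either ipsilateral array of the 72 h protocol, where their WT signal was below background and KO signal at least 8.48-fold and 3.8-fold higher. Arg1, Itih4 and Clec4d were above background on only 3 arrays, Fpr2 on 4, Chil4 on 5 and Bub1b on 2, so the size of these values is uncertain. Pop4 (-5.41, above background on 7 arrays, but not on KO ipsilateral 72 h and both WT contralateral arrays), Oxt (-1.86), Avp (-1.53), Spint1 (-1.34, adjusted p = 0.193) and Bub1b (-1.003) had the largest negative values, and none passed. Oxt, Avp, Spint1 and Bub1b are on chromosome 2, where the genotype calls gathered. Limma called 0 genes, with 359 at an unadjusted p under 0.05, and between 0 and 4 with the alternatives and with arrays left out. Pop4 ranged from -7.57 to -3.26 with single arrays left out. Its signal was 9.01 to 9.36 on the 7 arrays above background and 4.55 to 5.04 on the rest, so its value does not stand for a graded change. Both untreated arrays were among the 7, and why the signal was absent from the rest was not tested. The list of blood-borne myeloid cells was higher by camera (2 of 15 members adjusted over the list alone, median 0.43, camera adjusted p = 1.8e-06, adjusted p = 0.43 with an estimated correlation). Striatal neurons were lower (0 of 25 members adjusted over the list alone, median -0.26, camera adjusted p = 3.27e-06, adjusted p = 0.244 with an estimated correlation). They were among 13 list calls, none of which held with an estimated correlation. Across genes, the KO and WT hemisphere differences had a Pearson r of 0.854 under the 48 h protocol and 0.800 under the 72 h protocol.

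Within the ipsilateral hemispheres, with 1 array per genotype at each protocol and no test, 26 genes differed by at least 1 log2 unit in the same direction under both protocols, 12 higher and 14 lower in KO. The acute-phase gene Saa3 was higher in KO by 1.06 at 48 h and 2.82 at 72 h, and the neutrophil genes Fpr2 (1.43 at 48 h and at least 3.96-fold at 72 h) and S100a8 (1.26 and 1.84) and the macrophage gene Chil4 (1.23 and 2.04) were higher too. Such differences were not limited to ipsilateral tissue. In the 48 h contralateral hemispheres S100a8 was at least 5.25-fold and Saa3 at least 2.5-fold higher in KO, whereas in those of the 72 h protocol S100a8 was at least 1.82-fold lower. Both were below background in untreated brain. Ccl21b, Ccl21a, Stk4 and Pla2g4e were also on the higher side. Pygb, Cd93, Ahcy, Ttpal, Zcchc3, Oxt, Spint1 and Bub1b were the 8 lowest by mean. All 8 are on chromosome 2, where the genotype calls gathered, as are Stk4 and Pla2g4e. Of the 26 genes, 12 differed by as much in the untreated and both contralateral conditions. At 72 h, 69 genes were at least 1 unit higher and 25 lower in KO, against 13 and 19 at 48 h. In a principal component analysis of all tested genes, component 3 held 10.1% of the variance. The WT ipsilateral (18.3) and contralateral array (15.1) of the 72 h protocol stood apart there from the other arrays (-10.9 to 1.86). The larger counts at 72 h therefore cannot be told apart from a trait of these WT samples on both sides. Blood-borne myeloid genes had median differences of 0.39 at 48 h and 0.78 at 72 h, each above all 10000 random lists matched on mean expression. So were those of reactive astrocytes (0.17 and 0.69), chemokines (0.45 and 0.69) and phagocyte activation (0.16 and 0.31). Striatal neurons, at -0.27 and -0.25, lay below all of them under both protocols. Endothelium (0.070 and 0.60), activated endothelium (0.047 and 0.39) and matrix and scar (-0.100 and 0.53) lay above all of them at 72 h and at percentiles 96.8, 85.2 and 1.52 at 48 h, a difference that was not tested. Resting microglia (-0.22 and -0.12, percentiles 0.04 and 7.66) and complement (-0.22 and 0.16, percentiles 0.07 and 98.5) lay low at 48 h. Immediate early genes went opposite ways, with medians of -0.21 at 48 h and 0.25 at 72 h. The members of a list are not replicates, and the random lists do not keep the correlation between members. The percentiles therefore describe these arrays and do not measure an effect of genotype.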

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

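The tests of DNA around Cd93, of calls by chromosome, of DNA around the Ccl21 genes, of lymphatic vessels, of a glucocorticoid response and of carried-over ipsilateral tissue were chosen only after the result was seen, as was the use of splits within conditions alone. Several lists and genes drew attention because the hemisphere difference was not the same under both protocols or in both genotypes. Between the protocols, 48 h minus 72 h, the list medians past the camera threshold were -0.37 for resting microglia, -0.60 for phagocyte activation, -0.31 for complement, -0.28 for antigen presentation and -0.43 for cell cycle. For genotype by ipsilateral side they were 0.18 for chemokines, 0.19 for cytokines and receptors, -0.14 for resting microglia, 0.43 for blood-borne myeloid cells, 0.15 for the interferon response, 0.21 for reactive astrocytes and 0.23 for endothelium. Activated endothelium stood at 0.21, matrix and scar at 0.084, striatal neurons at -0.26, other brain regions at -0.15, stress at 0.12 and immediate early genes at 0.26. None of these list calls held with an estimated correlation, whose lowest adjusted p was 0.0652 between protocols and 0.244 for the interaction. Slc25a4 (difference 1.01), Cobl (0.86), Slc7a6os (0.89, but -0.036 with its other probe) and Sos2 (0.88) passed as higher in ipsilateral tissue at 48 h and lower at 72 h. Both genotypes had these signs, without a test within a genotype. The differences between protocols did not pass (limma adjusted p from 0.105 to 0.145). Among 3496 detected probes without a single gene name, which no comparison used, 371 passed in the 48 h and 175 in the 72 h hemisphere comparison, 1 in the protocol difference, 5 and 8 in the 48 h and 72 h contralateral comparisons and 23 in the genotype comparison.

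The gathering of genotype calls on chromosome 2 was weighed first. The model pairs the arrays of a condition, and 86 of 100 splits drawn at random put both arrays of a condition on the same side, so only the 16 splits within conditions are comparable. Of these, 1 reached the count of genes, the real split with 109, and the highest other gave 0. The other splits mix the genotypes unequally, so they keep part of the genotype difference and put the rest into the residuals. For the lists, 3 of the 16 gave as many as the real 12, and the highest other gave 16. With 16 splits no share under 5% can be reached. The odds ratio of 7.94 for chromosome 2 against the others is the gathering itself, so an effect of the lost protein cannot be told apart from other causes by it. DNA of the donor strain kept around Cd93 may account for the gathering, as the 200 nearest genes held 18 calls against 25 in the other 553 (odds ratio 2.09, 95% interval 1.05 to 4.09, Fisher's exact two-sided p = 0.0311). All but 3 of the calls on the chromosome lay in a single stretch around Cd93 that is wider than these 200 genes. Calls of that stretch therefore fell on both sides of the comparison, and the odds ratio is a weak measure of it. Its p-value also takes neighbouring genes as independent, which they may not be. The stretch was seen in the same data and was not tested. Sequence variants under single probes might add to the gathering, but the median ratio of 0.104 between second and first probes over 13 genes cannot show it. The first probe was the brighter and the one that passed, so a smaller change on the second can arise without variants. Called genes of other chromosomes were not compared. Of the 13 genes, 6 had ratios of their own above 0.6, so the variants do not cover all of them.

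The high Ccl21a and Ccl21b signal in KO brain was weighed next. Lymphatic vessels carried into the KO samples are argued against by a median of 0.14 over the 5 measured of 6 lymphatic markers, the highest being Prox1 at 0.25, although Lyve1 and Prox1 also stand in lists of the report. DNA of another strain around the Ccl21 genes cannot be told apart from other causes, because 1 call, Cntfr, among 21 neighbours against 7 of 539 leaves an odds ratio of 3.78 with an interval from 0.0803 to 31.9. A direct effect of the loss of Cd93 stays open as untested, and no test separated the copies of Ccl21 that a strain may carry.

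The rise of genes in contralateral hemispheres over untreated brain was the third pattern. Ipsilateral tissue carried into the contralateral samples was weighed by the calls as higher that were higher still in ipsilateral tissue. They made up 59.5% (19 of 28 at 48 h and 59 of 103 at 72 h). The median ipsilateral minus contralateral differences of the calls were 0.71 and 0.10. A gene called in both comparisons counts in each. These genes were picked for high contralateral signal. The same contralateral arrays enter the ipsilateral minus contralateral difference, which lowers the share in advance. The share therefore neither excludes nor shows carried-over tissue. A glucocorticoid response may contribute, as the medians of 14 measured genes, 0.38 at 48 h and 0.48 at 72 h, stood at percentile 100 of matched random lists in both comparisons. Without Fkbp5, Sgk1 and Map3k6, the members that passed in either comparison, a setting also added after seeing the data, the medians of the other 11 were 0.26 and 0.47, again at percentile 100, and Fkbp5, Gjb6, Mt1, Mt2, Cdkn1a, Ddit4 and Per1 also stand in lists of the report. The random lists do not keep the correlation between members, so the percentiles alone do not settle it. The untreated arrays were shared by both comparisons, and handling or dissection of the untreated brains stays open as untested.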

How the results depend on the processing

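Counts changed by up to 1.5 times are not repeated here. For the 48 h hemisphere comparison (1939 genes) they moved by more than 1.5 times to 4925 under median centring, 1267 with the value table of the authors and 3273 with the 4 arrays of the protocol alone. With the hemispheres of a genotype and protocol as a random block, a setting added after seeing the data, counts moved to 2915 in the 48 h (1939) and 2034 in the 72 h hemisphere comparison (1348), 28 in the protocol difference (0), 38 in the 72 h contralateral comparison (131), 52 in the genotype comparison (109) and 2 in the interaction (0). With those hemispheres averaged, also added then, the genotype comparison gave 36. The protocol difference (0 genes) gave 7 without background correction, 3 with the value table of the authors, 1 with detection on all 10 arrays, with every probe or with the 8 hemisphere arrays, and 6 with a variance trend. The 48 h contralateral comparison (33) gave 57 under median centring, 3603 with the value table of the authors, 1 with no detection filter and 78 with a variance trend. The 72 h contralateral comparison (131) gave 203 without background correction, 2073 with the value table of the authors, 4 with no filter and 307 with a variance trend. The rise with the value table of the authors follows from its scaling within pairs of arrays, which splits the contralateral and untreated arrays. The genotype comparison (109) gave 209 without background correction, 69 with no filter, 224 with a variance trend, 29 with genotype alone and 36 without chromosome 2, an alternative added after seeing the data. The interaction (0) gave 3 with the value table of the authors. With each array left out, counts ranged from 585 to 2024 (48 h hemispheres), 582 to 1368 (72 h hemispheres), 0 to 4 (protocol difference), 3 to 51 (48 h contralateral), 4 to 99 (72 h contralateral), 44 to 136 (genotype) and 0 to 4 (interaction). The protocol difference gave 4 without either KO array of the 72 h protocol, and the interaction 4 without either ipsilateral array of the 48 h protocol. Lists past the threshold fell to 0 with an estimated correlation in all comparisons but the 72 h hemispheres, where 5 held, and to 5 under median centring in the 72 h contralateral comparison. Genes that differed without a test (26) became 12 without background correction, 15 with the value table of the authors and 11 with detection on all arrays. Among single genes, the directions that reversed were of values that had not passed. Among lists past the camera threshold, medians changed sign under median centring for general (-0.26 to 0.13) and cortical neurons (-0.24 to 0.18) in the 48 h hemispheres. Complement (-0.31 to 0.023) and antigen presentation (-0.28 to 9e-04) did so in the protocol difference, and myelin (-0.15 to 0.024) in the 72 h contralateral comparison. With the value table of the authors it did so there too (0.14), as did striatal neurons (-0.12 to 0.23), myelin (-0.13 to 0.24) and immediate early genes (-0.20 to 0.16) in the 48 h contralateral comparison. With the value table of the authors, Rgs9 (0.063) and Cd93 (0.012) reversed in the 48 h contralateral comparison, and under median centring Ccl21a (0.072) and Ccl21b (0.14) in the interaction. With each array left out, the protocol difference ranged from -0.40 to 0.72 for Cd93, -0.11 to 0.42 for Ccl21a, -0.15 to 0.36 for Ccl21b and -0.071 to 0.38 for Gfap, and the 48 h contralateral comparison from -0.58 to 0.093 for Cd93 and -0.15 to 0.36 for Ccl21b. The genotype comparison ranged from -0.14 to 0.021 for Gfap. The interaction ranged from -0.011 to 0.96 for Pecam1, -0.0021 to 2.54 for Selp, -0.032 to 1.36 for Lrg1, -0.054 to 0.87 for Mt2 and -0.10 to 1.01 for Junb. Of the values of single genes under the other alternatives, 3539 kept direction and side of the threshold, 167 became stronger and 123 weaker. Beyond the scaling named above, the cause was not tested. Signal over background limits genes such as Il6 and Tnf, which were below it on all arrays.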

Other observations

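Igfbp2, an insulin-like growth factor binding protein gene, was higher in ipsilateral tissue by 1.29 under the 72 h protocol and 0.64 under the 48 h protocol, and lower in the contralateral hemispheres of the 72 h protocol than in untreated brain (-0.62, limma adjusted p = 0.0441). Of the glucocorticoid-responsive genes, Sgk1 was higher in contralateral tissue than in untreated brain by 1.18 at 48 h and 0.90 at 72 h, and Map3k6 by 1.08 at 72 h (limma adjusted p = 0.0127, 0.0396 and 0.0406). The other probe of Sgk1, above background on all 10 arrays, was at 1.43 and 0.94 but did not pass (adjusted p = 0.0962 and 0.135). The cold-inducible genes Rbm3 (0.75, limma adjusted p = 0.00123) and Cirbp (0.75, limma adjusted p = 0.00445) were higher in KO than in WT brain over the 5 conditions. All of these genes were singled out after their values were seen.

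The chemokine list without Ccl21a and Ccl21b, an alternative added after seeing the data, had 16 members and a median KO minus WT difference of 0.36 (camera adjusted p = 0.0099, adjusted p = 0.447 with an estimated correlation). A second Cd93 probe had lower values in KO than in WT in all 5 conditions, but was above background on only 3 of the 10 arrays, both WT ipsilateral arrays and the KO ipsilateral array of the 48 h protocol.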
